A study of Rattus norvegicus with 8 samples.

How the data were processed

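Total RNA from mucosal scrapings of the distal colon of rats was hybridised to Affymetrix rat expression arrays after 11 weeks on a control diet (4 arrays) or on a diet with 10 g of quercetin per kg (4 arrays). Groups and replicate numbers were read from the sample titles. The labels do not state outright that each array holds the RNA of a separate rat, so the p-values measure the spread between these 8 samples.

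The deposited values are linear intensity values, 1 per probe set and array, made with MAS5 per the submitters' processing notes. MAS5 combines the probes of a probe set into 1 signal and scales each array, and in the deposited intensity table the mean signal with 2% trimmed at either end was 200.1 on each array. Other processing steps, the scanner settings and a genome build are not given in the sources used here, so no coordinates are printed. The scaling makes arrays comparable only if most transcripts hold their level, and MAS5 signals of dim probe sets scatter widely on a log scale.

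Of 31099 probe sets, 57 array controls were left out of the tests. Signals were transformed to log2(signal + 16), which understates the fold change of dim probe sets. The array medians of log2 signal lay between 5.51 and 5.91, a range of 0.407 and under the limit of 0.5 set beforehand for adding a quantile normalisation, so the values were kept as deposited. The upper 60% of probe sets by mean over all 8 arrays were tested, which left 18625 probe sets with a mean log2 value of at least 5.504, a signal of about 29.4. Quercetin was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene is from this limma fit unless another test is named. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.222, and its 95% interval reached 0.481 to either side.

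Gene symbols came from the platform annotation, which gave 1 symbol for 20826 probe sets, several for 436 and none for 9780. The Entrez identifiers of 20764 probe sets were found in a RefSeq gene table (assembly GRCr8), and 0 symbols changed. Probe sets with several symbols or none were tested and left unnamed. Where a gene had several probe sets, the brightest stood for it, which gave 10266 genes.

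Before the data were examined, 44 gene lists (31 of pathways, 13 of cell types) were written down, along with the tests, the alternatives and the rule for naming genes. The choice of 9 pathway lists drew on themes recalled from the study of these samples, 8 of which held enough genes to be tested. Such lists are not independent evidence of direction. A list needed 5 measured genes, and 41 were tested with camera at a preset inter-gene correlation of 0.01, then with camera's estimated correlation and with fry. List means per array were also compared by an exact permutation test, two-sided, whose smallest possible p is 0.0286. Adjusted over 41 lists, a p of that size can pass only if most of the lists reach it.

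The naming rule took, in each direction, up to 12 genes with an adjusted p under 0.05 and no overlap between the groups. Where fewer than 12 passed, it took all that passed and filled up to 6 with the smallest p, named as not passing. For each list described it added up to 4 passing members with the largest change, or, where none passed, the 2 with the smallest p, as values. Genes named outside this rule are said to have been chosen after their values were seen.

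The steps were tested on simulated data with the means and residual spread of the 18625 probe sets, in 10 runs with 200 changed probe sets each. Of changes of 0.5, 1, 1.5 and 2 on the log2 scale in this comparison, 4%, 42.6%, 70.4% and 84.8% were recovered, and 4.62% of calls were false. A list shifted by 0.3 was called in 10 of 10 runs with either correlation. The simulated genes were independent, which those of a real tissue are not.

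The alternatives were pseudocounts of 1 and 64, quantile normalisation, median centring, no filter, the upper 40% of probe sets, array weights, the replicate number as a block, eBayes without the trend, 1 probe set per gene, the mean of a gene's probe sets, and each array left out in turn. After the data were seen, a fit with the GAPDH 3' to 5' signal ratio as a covariate and a fit without control arrays 1 and 2 were added.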

Results

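The series asked which transcripts of the rat colon mucosa differ after long-term feeding of quercetin, a plant flavonol, from those after a control diet. Arrays of 4 quercetin-fed and 4 control samples were compared. Pairwise correlations over the tested probe sets were 0.914 to 0.965 within the control group, 0.952 to 0.966 within the quercetin group and 0.914 to 0.965 between the groups. Control array 2 had the lowest mean correlation with the other arrays, 0.927. It had the highest 3' to 5' signal ratios of beta-actin and GAPDH, which rise when RNA is shortened or copied incompletely. Its beta-actin ratio was 21.4, against 8.65 to 12.4 on the other control arrays and 6.79 to 9.12 on the quercetin arrays. Its GAPDH ratio was 3.79, against 1.58 to 2.36 on all others. Apart from control array 2, the beta-actin ratio was still lower in the quercetin group on average.

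Per2, a core repressor of the circadian clock, fell by 1.53 on the log2 scale in the colon of quercetin-fed rats (SE 0.15, adjusted p = 0.00269). Its signal was 669 ± 9.67 (SD, n = 4) in the control group and 223 ± 40.03 (SD, n = 4) in the quercetin group, 0.346 times the control level on the transformed scale, and all 4 quercetin arrays lay below all 4 control arrays. The only other probe set past the threshold, 1379023_at, has no gene symbol here. It fell by 1.35 (SE 0.180, adjusted p = 0.0447), from a signal of 268 ± 49.8 (SD, n = 4) to 95.1 ± 11.8 (SD, n = 4). Its call was lost in each of the 8 fits that left out 1 array, with adjusted p-values of 0.0526 to 0.238 and log2 fold changes of -1.43 to -1.24.

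Across the 18625 probe sets tested, 2 passed limma's adjusted threshold, 0 of them higher and 2 lower in quercetin. At an unadjusted p under 0.05 there were 2003 probe sets, 939 higher and 1064 lower, where chance gives 931. The groups did not overlap in 1190 probe sets, 6.39% of those tested, against 2.86% by chance. Without control arrays 1 and 2, both of which stand apart from the rest, 0 probe sets passed, and Per2 then had a log2 fold change of -1.52 with an adjusted p of 0.0750.

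The other genes with the smallest p did not pass. On the higher side these were M6pr, a receptor that carries enzymes to lysosomes (log2 fold change 0.68, SE 0.116, adjusted p = 0.16), Btd, which recycles biotin (1.66), Prelid1, a mitochondrial lipid transfer protein (0.64), Abcc3, an efflux pump for conjugates (0.76), Clpb, a mitochondrial chaperone (1.08), and Cat, the hydrogen peroxide scavenger catalase (0.72). The other 2 probe sets of Clpb had values of -0.27 and -0.22. On the lower side were Trib3, a pseudokinase of the stress response (-0.97, SE 0.167, adjusted p = 0.16), Fosb, an immediate early transcription factor (-1.38), Dync1li1, a dynein subunit (-0.90), Cry1, a clock repressor (-0.82), and Tcim (-0.83). Each of these 11 genes had no overlap between the groups.

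The circadian clock list passed camera in the lower direction (adjusted p = 0.00496, adjusted p = 0.814 with an estimated correlation), with members on both sides. The fry adjusted p was 8.34e-05 for change in either direction and 0.175 for a shift in 1 direction. Of its 15 measured genes, 9 were lower and 6 higher, with a mean log2 fold change of -0.27. Only Per2 passed over all genes, and 5 passed when adjusted over the list alone. Besides Per2 and Cry1, those were Npas2 (-0.63, SE 0.15), an activator of clock genes, and the repressors Nr1d1 (1.19, SE 0.305) and Nr1d2 (0.66, SE 0.223), which had higher signals in quercetin. These 3 genes, and Per3 (-0.97), Cry2 (-0.47), Clock (0.20) and Bmal1 (0.05), were chosen after their values were seen. Bmal1 and Clock, the activator pair at the core of the clock, had adjusted p-values over the list alone of 0.891 and 0.183, and the sign of Bmal1 turned in 3 of the alternatives. Another Clock probe set had -0.02, and another of Nr1d2 0.39. The call of the list was lost without control array 1 (mean -0.23, adjusted p = 0.0547), without quercetin array 1 (-0.18, 0.0591) and without the filter on dim probe sets (-0.15, 0.0889), and with the upper 40% of probe sets the mean was -0.17 (adjusted p = 0.0309). Without quercetin array 1 the value of Per3 was -0.42.

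**Figure D1:**
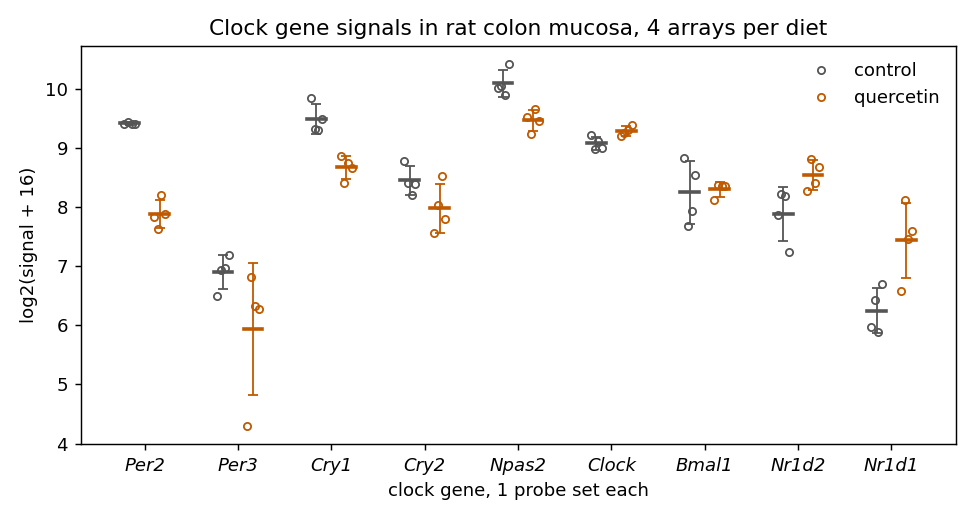
Signals of 9 clock genes on each array, as log2(signal + 16), with points for the 4 arrays of each diet, thick bars for means and thin bars for SD. The 4 control points of Per2 lie together, with an SD of 0.0202 on the log2 scale, above all 4 quercetin points, while Nr1d1 and Nr1d2 lie higher in quercetin on average.

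The list of fatty acid oxidation genes and targets of PPAR alpha, a lipid-sensing nuclear receptor, shifted higher (camera adjusted p = 9.56e-08, adjusted p = 0.724 with an estimated correlation). Of 36 measured genes 30 were higher, by a list mean of 0.33, and 0 passed limma over all genes while 19 had an unadjusted p under 0.05. Adjusted over the list alone 14 passed, all higher; the list was chosen with the study in mind and this count is not independent evidence. Its list mean was higher on every quercetin array than on every control array (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.234). Slc25a20, the carnitine carrier of mitochondria, had a log2 fold change of 0.69 (SE 0.148), and Eci1, an isomerase of fatty acid oxidation, 0.60 (SE 0.162), with 0.21 on another probe set. Chosen after their values were seen, Cpt2 had 0.64 (SE 0.196) and Fabp1, the liver-type fatty acid binding protein, 2.50 (SE 0.828), with a quercetin signal of 8284 ± 6551 (SD, n = 4) against 1959 ± 2022 (SD, n = 4). Absorptive colonocyte markers had a list mean of 0.11 and did not pass (camera adjusted p = 0.709).

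Antioxidant genes controlled by NRF2 shifted higher (camera adjusted p = 0.000223, adjusted p = 0.724 with an estimated correlation), with 17 of 19 genes higher and a mean of 0.32. None of the 19 passed limma over all genes, and 7 had an unadjusted p under 0.05. The other 12 included the 2 lower genes, Srxn1 (-0.29) and Txn1 (-0.25), and Gclm (0.03), Gclc (0.26) and Hmox1 (0.26). These 5 were chosen after their values were seen. Adjusted over the list alone 5 passed, among them Abcc3 (0.76), Cat (0.72) and Gpx2 (0.46, chosen after its values were seen), a glutathione peroxidase of the gut; the list was chosen with the study in mind. The exact permutation p of the list mean was 0.0286 (adjusted p = 0.234). Phase II conjugation enzymes also shifted higher (camera adjusted p = 0.0198, adjusted p = 0.814 with an estimated correlation), with 24 of 28 genes higher and a mean of 0.25, and 0 passed adjusted over the list alone or over all genes, 5 having an unadjusted p under 0.05. Its leading members were the glutathione transferases Gstp1 (0.51) and Gstm4 (0.45). That call was lost without control array 2 (adjusted p = 0.203) and without quercetin array 1 (adjusted p = 0.316).

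Proliferation genes shifted higher (camera adjusted p = 5.2e-09, adjusted p = 0.814 with an estimated correlation). Of 36 measured genes 35 were higher, with a mean of 0.52, while 0 passed limma over all genes, 11 had an unadjusted p under 0.05, and 3 passed adjusted over the list alone. The list was chosen with the study in mind, so this count is not independent evidence. The values of Foxm1, a mitotic transcription factor, and Cdk1, the mitotic kinase, were 1.26 (SE 0.340) and 0.92 (SE 0.249). Ccnd2, a cyclin of the growth phase, was the member that was lower (-0.55), and Mki67 had 0.82 (SE 0.381), or 0.33 without control array 1; both were chosen after their values were seen. Control array 1 had a list mean 1.02 below the mean of the 8 arrays, and without it the list mean fell from 0.52 to 0.27, with a camera adjusted p of 0.000178. The exact permutation p of the list mean was 0.171. DNA repair genes shifted higher (camera adjusted p = 0.00821, adjusted p = 0.814 with an estimated correlation), with 21 of 23 higher, a mean of 0.26, 0 past limma over all genes, 3 with an unadjusted p under 0.05, and 1, Parp1 (0.56, SE 0.144), adjusted over the list alone; Mutyh had 0.83 (SE 0.370). That list too was chosen with the study in mind, and its call was lost without control array 1 (adjusted p = 0.129).

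Antigen presentation genes of MHC class II shifted higher (camera adjusted p = 0.00465, adjusted p = 0.814 with an estimated correlation), with 9 of 9 genes higher and a mean of 0.38. Adjusted over the list alone 3 passed, and 0 passed limma over all genes, 4 having an unadjusted p under 0.05. Cd74, the invariant chain, had a log2 fold change of 0.64 (SE 0.193) and RT1-Bb, a class II chain, 0.56 (SE 0.181). Control array 2 had the lowest list mean, -0.50 relative to the mean of the 8 arrays, and without it the call was lost (adjusted p = 0.145). Markers of macrophages and dendritic cells, which carry MHC class II and share no gene with this list, had 6 of 8 genes higher and a mean of 0.19. Their list mean was higher on every quercetin array than on every control array (exact permutation p = 0.0286, adjusted p = 0.234), while camera gave an adjusted p of 0.521 and fry 0.164.

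**Figure D2:**
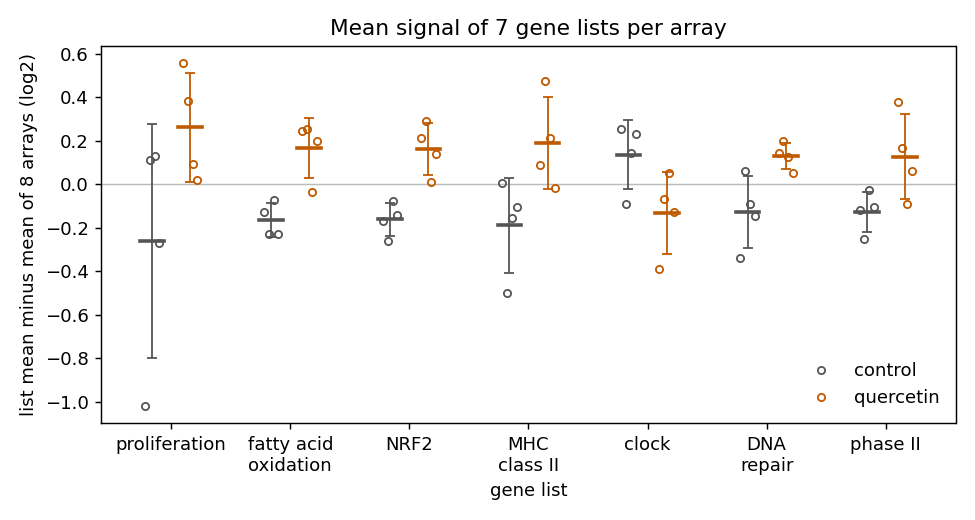
Mean log2 signal of the 7 lists that passed camera, per array and relative to the mean of all 8 arrays, with points for the 4 arrays of each diet, thick bars for means and thin bars for SD. The quercetin and control points do not overlap for fatty acid oxidation and NRF2, and control array 1 lies at -1.02 for proliferation.

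In all, 7 of 41 lists passed camera with the preset correlation, 6 higher and 1 lower, of which 4 were chosen with the study in mind. With an estimated correlation 0 passed (2 had an unadjusted p under 0.05), and with fry 0 passed for a shift in 1 direction (7 unadjusted) and 6 for change in either direction. The list count was no larger than other groupings of the same arrays give: 20 of the 35 splits into 4 and 4 arrays had at least 7 lists past camera.

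Other pathways did not pass with all arrays and the main settings. Immediate early and MAPK response genes had a mean of -0.12 (camera adjusted p = 0.124, fry adjusted p = 0.00125 for change in either direction). The list passed camera without control array 2 (mean -0.20, adjusted p = 0.00186), without quercetin array 2 (-0.15, 0.0209) and with array weights (-0.15, 0.0394). In the fit with all arrays 3 genes were past the threshold adjusted over the list alone: Fosb, Dusp6, a phosphatase that restrains ERK (-1.10, SE 0.253), and Fos (-0.76, SE 0.218, chosen after its values were seen). Unfolded protein response genes had 12 higher and 12 lower (camera adjusted p = 0.498, fry adjusted p = 6.3e-05 for change in either direction), with Trib3 at -0.97 and the chaperone Pdia3 at 0.73, though another Pdia3 probe set had -0.44. Of the lists chosen with the study in mind, glycolysis had a mean of 0.09 (camera adjusted p = 0.786; Pfkl 0.45, Gpi 0.35), p53 targets -0.02 (0.889; Tp53i11 0.43, Ei24 0.20), kinases of the MAPK cascade 0.02 (0.889; Map2k3 -0.37, Map3k1 0.37, with -0.03 on another probe set) and phase I drug metabolism 0.16 (0.332; Maoa 0.49, Cbr3 0.67). Efflux and bile acid transporters had a mean of 0.15 (camera adjusted p = 0.786, fry adjusted p = 0.0142 for change in either direction), with Abcc3 at 0.76 and Abcc1 at -0.67. Inflammation genes of NF-kB had 12 of 15 higher and a mean of 0.14 (camera adjusted p = 0.709, Tnfaip3 -0.40, Nfkbia 0.39). Their list mean was higher on every quercetin array than on every control array (exact permutation p = 0.0286, adjusted p = 0.234). Of the 41 lists 5 had an exact permutation p under 0.05, and 0 passed after adjustment. With a smallest possible p of 0.0286, a list could pass only if most of the 41 reached it, so that 0 decides nothing.

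Markers of other cell types were measured as a check on what the scrapings held. Of 12 cell type lists tested, 0 passed camera and 0 had an unadjusted camera p under 0.05. With fry and with the exact permutation test of the list mean 0 passed after adjustment, and 1 had an unadjusted p under 0.05 in each, the macrophage and dendritic cell list. For the exact test, passing after adjustment was all but impossible with so few arrays. The means of the 12 lists ran from -0.07 to 0.29 and their camera adjusted p from 0.521 to 0.889. Smooth muscle markers had a mean of 0.02 (Tpm1 -0.32, Mylk -0.42), though the other 4 Tpm1 probe sets ran from -1.41 to 0.35, and absorptive markers included Slc9a3 at 0.72 and Slc16a1 at 0.43. Among all 41 lists tested, of pathways and cell types together, the median and the camera direction differed in sign in 5, and none of those passed. Lists of Ah receptor targets (4 genes), blood cell markers (2) and ketogenesis (3) had too few measured genes to test; Nqo1, an Ah receptor and NRF2 target, had 0.44 (SE 0.279) and Nfe2l2, which encodes NRF2, -0.13 (SE 0.155).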

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

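The tests on the RNA quality of control array 2 as a source of the clock difference, and on control array 1 and the crypt base as sources of the proliferation difference, were chosen after the results were seen, as were the split counts at an unadjusted p, the glucocorticoid mean with Sgk1 and Dusp1, and the crypt base value on control array 1. The other tests on the clock, the proliferation genes and control array 2 were set down after those patterns had been noticed, but before the values they measure were computed. Among 210 groups of 4 arrays (59 genes, 41 lists and 5 array measures, in each diet), 14 had 1 array far from the other 3, where chance gives about 10.5. The figure given for each is the gap to the nearest array as a share of the range.

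Single arrays lay low for Trib3 (control array 4, 0.953), Tcim (quercetin array 2, 0.885), Gpx2 (control array 1, 0.881), Ccnd2 (control array 3, 0.853), Bmal1 (quercetin array 1, 0.928) and Fos (quercetin array 2, 0.881). They lay high for Cd74 (quercetin array 2, 0.897), Tp53i11 (control array 2, 0.845), Map2k3 (quercetin array 3, 0.865) and Scd2, a fatty acid desaturase (control array 1, 0.869). Among list means, smooth muscle was high on control array 1 (0.887), fibroblast and matrix markers were low on quercetin array 4 (0.865) and apoptosis genes were low on control array 2 (0.831). The 3' to 5' ratio of hexokinase was high on quercetin array 4, at 6.05 against 2.16 to 2.37 on the other quercetin arrays (0.947).

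The count of 2 probe sets past the threshold was reached by 2 of the 35 splits of the 8 arrays into 4 and 4, the real one included, so chance cannot be excluded for it; the highest other split gave 6. That split set control arrays 1 and 4 and quercetin arrays 3 and 4 against the rest; no cause of its count was tested. The count of 7 lists past camera was reached by 20 of the 35 splits, the highest other giving 14, so chance cannot be excluded there either. At an unadjusted p under 0.05 the real split had the most probe sets, 2003 against 1978 in the highest other, but at an unadjusted p under 0.01 it had 552 against 557, and 2 of the 35 splits had as many.

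Control array 2 stood apart from the other arrays. The smooth muscle markers that were measured, 17 of 28, showed no excess. Their list mean minus that of the other controls was -0.0499 on the log2 scale, within the range of the rest. Actg2, Tagln, Cnn1 and Myl9 were among those not measured, so smooth muscle in the scraping is not excluded. Shortened RNA may account in part for the distance of control array 2. Of 3 control transcripts 2 had a 3' to 5' ratio above all other arrays, and hexokinase did not, so the ratios leave it open. For lymphoid tissue, the B cell list was the highest of the 8 arrays, with an excess over the other controls of 0.0919. The T cell list had an excess of 0.290 and was within range, which also leaves this explanation open. No biological explanation was tested, as the design gives none for a single array.

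The clock genes differed between the diets. The mean absolute change of the 7 clock genes with an unadjusted p under 0.05 was 1.04 times as large without control array 2. Those genes were picked by p in the fit with that array, so the ratio could hardly have fallen far and decides nothing. Over all 15 measured clock genes, whatever their p, the list mean was -0.27 with all arrays and -0.34 without control array 2. The shift of the list thus did not rest on that array. A difference in the time of sampling or in clock phase could give lower Per2, Cry1 and Npas2 beside higher Nr1d1 and Nr1d2; the 2 output genes dimmer than the filter, Dbp and Hlf, had a mean log2 fold change of 0.355 (exact permutation p = 0.200), which does not decide it. A lower glucocorticoid response was also left open, with a mean of -0.151 over 8 induced genes (exact permutation p = 0.371). Values of 2 further induced genes, Sgk1 (-0.89) and Dusp1 (-0.45, with -0.10 on another probe set), had been seen before that test was written, and they were left out of it; with them the mean over 10 genes was -0.255 (exact permutation p = 0.171). Sampling time is not given in the sources used here, so if it followed the groups, it and an effect of the diet cannot be told apart.

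Proliferation genes were higher in quercetin. The GAPDH ratio is argued against as the source, since the list mean with it as a covariate was 1.13 times that without. The beta-actin ratio, 8.65 to 21.4 on the control arrays and 6.79 to 9.12 on the quercetin arrays, was not tested as a covariate. RNA quality beyond the GAPDH ratio therefore stays open. Control array 1 may carry much of it: without that array the mean was 0.520 times the value with all arrays. A larger share of crypt base in the quercetin scrapings was left open by the list of Wnt targets and crypt base genes. Its 14 measured genes of 22 had a mean log2 fold change of 0.113 (exact permutation p = 0.714). Lgr5, Ascl2, Ephb2 and Olfm4 were among those not measured, so the list says little about the share of crypt base. On control array 1 the 14 measured genes lay low as well, with a mean minus that of the other controls of -0.824. An effect of the diet stays open as well.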

How the results depend on the processing

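The fit with the GAPDH ratio as a covariate and the fit without control arrays 1 and 2 were chosen after seeing the data. The count of 2 changed probe sets became 1 with a pseudocount of 1, quantile normalisation, median centring, no filter, eBayes without the trend and 1 probe set per gene, and 0 without control arrays 1 and 2, where fewer arrays were tested; a pseudocount of 64 gave 3, all lower, and leaving out each array in turn gave 1 to 2, of which 1 was higher in quercetin without control array 4 and 0 were higher in the other fits. The unnamed probe set passed in 0 of those 8 fits, so where they gave 2 the second call was another probe set. With the replicate number as a block 1 probe set passed. Once the group means were taken out, same-numbered arrays correlated at -0.0234, 0.163, -0.151 and 0.138. Of 8 arrays 3 correlated best with their own number, which gives no sign that the numbers pair the samples. Per2 kept its direction in each of these settings and its adjusted p stayed under the threshold except without control arrays 1 and 2 (0.0750). The count of 7 lists became 0 with an estimated correlation and 0 with fry, and stayed within 5 to 9 in the other settings, where fatty acid oxidation, NRF2 and proliferation kept their calls. Those settings all used camera with the preset correlation of 0.01, so they do not test that choice. The estimated correlation was 0.584 for proliferation, 0.153 for fatty acid oxidation and 0.0623 for NRF2. Phase II also lost its call with array weights (adjusted p = 0.0954) and without control arrays 1 and 2 (0.0775). Of 22 pathway lists that did not pass, 4 passed in some setting: TCA cycle and oxidative phosphorylation without control array 1, and cholesterol synthesis and immediate early genes without control array 2, without quercetin array 2 and in 1 further setting each. Of 1115 values of 59 of the named genes under these settings, 1111 kept their direction and side. Bmal1 turned to -0.14 without control array 2, -0.05 without control array 3 and -0.026 with the GAPDH covariate. For Bmal1, leaving out each array in turn gave -0.14 to 0.24. Apart from settings that test fewer samples, the cause of these changes was not tested. The number of probe sets at an unadjusted p under 0.01 went from 552 to 848 with the GAPDH covariate, 304 without control arrays 1 and 2 and 356 without quercetin array 2. Dim probe sets limit the rest: 12417 were not tested.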

Other observations

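Antimicrobial genes of the mucosa were not described as a group above. Of 14 measured genes 9 were higher in quercetin, with a mean log2 fold change of 0.44 that was higher on every quercetin array than on every control array (exact permutation p = 0.0286, the smallest possible, adjusted p = 0.234), and the list did not pass camera (adjusted p = 0.324). Reg3g, a secreted lectin that binds bacteria, had a log2 fold change of 2.32 (SE 0.838), with a signal of 701 ± 984 (SD, n = 4) in quercetin and 49.7 ± 34.5 (SD, n = 4) in control. Its relative Reg3b, chosen after its values were seen, had 1.78 (SE 0.766), and Lyz2, a lysozyme, 0.57 (SE 0.211). Much of the list mean came from Reg3g and Reg3b. For Reg3g the signal SD within the quercetin group was larger than the difference between the group means, and on the log2 scale the quercetin SD was 2.31. Its quercetin signals were 535, 2139, 59.2 and 72.4, and without quercetin array 2 the log2 fold changes were 1.37 for Reg3g and 0.81 for Reg3b.

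Lipid synthesis genes did not shift as a list (camera adjusted p = 0.932), with Scd2 at -0.87 (SE 0.186), the 1 member past the threshold adjusted over the list alone, though its other 3 probe sets had -0.32, -0.29 and -0.25, and Lpin1, a phosphatidate phosphatase, at 0.56 (SE 0.215), though another Lpin1 probe set had -0.08.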
